A study of Cupriavidus metallidurans CH34 with 9 samples.

How the data were processed

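Total RNA from Cupriavidus metallidurans was measured on 9 1-colour Agilent expression arrays, 3 each for strain AE104 with zinc, its deletion mutant AE104(Δzur), here called Δzur, without added zinc and Δzur with zinc. AE104 is a derivative of strain CH34 that lacks its large plasmids, and zur encodes a zinc-sensing repressor of zinc uptake genes. Per the labels, cells grew in mineral salts medium with 0.2% gluconate to a turbidity of 100 Klett and received 100 µM ZnCl2 for 10 min, RNA was purified on columns with DNase digestion, checked for residual DNA by PCR and labelled with Cy3. AE104 without added zinc was not among the samples, so whether the response to zinc depends on zur was not tested. The labels do not say whether replicates were separate cultures, and the p-values therefore measure the spread between these samples.

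Per the file headers, the scanner files hold spot intensities quantified with Agilent Feature Extraction 10.7.3.1, with spatial and multiplicative detrending, and the processed intensity of each probe is corrected for background within its array but not scaled between arrays. The authors' table of deposited values holds linear intensities per feature. Set against the scanner files, these were the mean over a feature's probes of spot minus local background brightness, scaled so that each array summed to about the same total, within 1% for over 99% of the brighter features, and a few values were slightly negative. These deposited intensities served only as an alternative, with negative values set to 0 and 0.01 added before the log2.

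The arrays held 15207 probes besides 536 control spots. The names in the files gave 9736 features after 364 numbered parts of long genes were merged with their gene. Of these, 6319 were genes, 5945 known by locus tag, 66 by an RNA locus tag and 308 by symbol, and 3417 were intergenic. No reference annotation was used here, so genes without a symbol carry no function or position, and zur itself, its reported targets and the metal transport and resistance genes could not be told from other locus tags. The planned check of the labels on the zur signal was therefore not run. In all, 3281 genes had 1 probe, 2919 had 2 and 119 had more.

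The log2 of the processed intensity minus the log2 of the array's 75th percentile over all non-control probes was averaged over the probes of a gene. Spots marked as outliers were left out. A gene was tested when at least 1 of its probes was well above background, by the scanner software's own call, on all 3 arrays of at least 1 group, which held for 5054 genes. Models were fitted with limma 3.58.1 in R 4.3.3 to all 9 arrays with 1 mean per group, and 3 contrasts were tested two-sided with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. The residual degrees of freedom were 6, and the empirical Bayes prior added 3.24. Errors given with log2 differences are standard errors from this model. Where no array of a group detected a gene, the fold was also computed as a lower bound against the lowest signal called well above background on those arrays. The number of arrays, 3 per group, limits the precision. In simulated data with 5051 genes, of which 200 were changed, the model recovered 31.3% of genes with a log2 change of 0.5, 80.6% with a change of 1 and 95.5% with a change of 2 in the zinc contrast, and 5.48% of its calls were false. The simulated noise was independent between genes and had no slide effect, and fewer genes were changed than were called for zinc. These rates therefore need not hold for the real arrays.

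The comparisons, tests, alternatives and the rule for named genes were fixed before the data were examined. In the contrasts of zinc with no zinc and of Δzur with AE104, the rule named the 10 largest called rises and falls whose arrays did not overlap, and 5 of each in the contrast that mixes both factors. It also named up to 4 called members of each gene list, or the 2 with the smallest p where none was called. Of the genes known by locus tag, at most 2 rises and 2 falls per comparison are printed. Gene lists fixed beforehand covered ribosomal proteins, chaperones and heat shock proteases, flagella and motility, the respiratory chain and ATP synthase, zinc-dependent enzymes and their paralogs, hydrogenase, urease and nickel, DNA repair, polyhydroxybutyrate and central carbon, sulfur assimilation and phosphate uptake. The last pair had 2 members each, too few for a set test. The lists of Zur and COG0523 loci, metal uptake, metal efflux and resistance, oxidative stress, iron and sigma factors had 0 members among the symbols. Planned lists of mobile elements and plasmid genes rest on products and replicons that the files do not give for genes, and were not run. Further lists were drawn up once the symbols were known but before any comparison was computed, namely aminoacyl-tRNA synthetases, translation factors, transcription core, DNA replication, amino acid, nucleotide, cell wall and cofactor synthesis, protein export, iron-sulfur cluster assembly, cobalamin synthesis, tRNA modification and the RNA locus tags. The gene rpmJ is in both the ribosomal and the zinc-dependent list, and gltD, cysS and cysM are each in 2 lists. Lists with at least 3 tested members were tested with camera in limma at a preset inter-gene correlation of 0.01, adjusted over the 21 lists of a contrast, and again with an estimated correlation and with fry.

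The alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter and a stricter filter on dim probes, the brightest probe of a gene, a trended robust prior, each pair of groups alone, the replicate number as a block, the slide as a block, the authors' values, a minimum of 2-fold and leaving out each array. The arrays came from 2 slides. Slide 1 held the 3 AE104 arrays and 2 of untreated Δzur, and slide 2 held the third untreated Δzur array and the 3 of Δzur with zinc, so no slide held both AE104 and zinc-treated Δzur. After the data were seen, comparisons within a slide, numbered gene parts kept apart, intergenic features tested together with genes, and the exclusion of segments of consecutive locus tags were added. The slide as a block was planned for the tests of genes but not for the gene lists. Segments were windows of 11 tested locus tags in number order with at least 7 that differed at least 2-fold, in the same direction, between AE104 and each Δzur group, and 1000 permutations of the tag order gave the chance level. The search was repeated without the untreated arrays, on Δzur with zinc against AE104, and without each AE104 array, so that the arrays left out could be tested on the segments found. Intervals of medians over genes are 95% bootstrap intervals from 2000 draws, which cover the spread over genes and not that between arrays. Intervals over arrays are 95% t intervals of the difference between groups in the list's median per array. For these tests, undetected values were set to the lowest signal called well above background on the array, and intervals of shares are exact binomial (Clopper-Pearson). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.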

Results

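Transcript levels of Cupriavidus metallidurans, a metal-resistant soil bacterium, were measured in strain AE104 with zinc, in its Δzur mutant without added zinc and in the mutant with zinc, with 3 arrays in each group. Between 9859 and 11713 of the 15207 probes were well above background on an array. The 75th percentile of the processed intensity was 111 ± 8.75 (SD, n = 3) in AE104 with zinc, 93.6 ± 20.5 (SD, n = 3) in untreated Δzur and 116 ± 6.41 (SD, n = 3) in Δzur with zinc. Across genes, which are not independent replicates, log2 values of arrays of the same group correlated at 0.982 to 0.990 and those of different groups at 0.872 to 0.963. The median SD of a gene within a group was 0.15 in AE104, 0.17 in untreated Δzur and 0.16 in Δzur with zinc, on the log2 scale. The first principal component held 66.9% of the variance and separated AE104 from the mutant, and the second held 17.4% and separated the mutant's treatments.

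The response of the mutant to 10 min of zinc was the first question. With zinc, transcripts of the phosphate transporter, of iron-sulfur cluster chaperones and of the HslU heat shock ATPase were higher, and those of all 47 measured ribosomal proteins and of the small subunit of glutamate synthase were lower. The gene Rmet_3620 had the largest rise, 129-fold (log2 difference 7.02 ± 0.15, SE, adjusted p = 1.64e-08), from a mean log2 signal of -0.62 in untreated to 6.40 in treated Δzur. Rmet_4026 rose by 4.85 ± 0.20 on the log2 scale. Rmet_4564 fell by 4.06 ± 0.12 and Rmet_3144 fell by 3.85 ± 0.12, from mean log2 signals of 4.34 and 4.21 in untreated cells. For each gene named as changed, all 3 arrays of one group lay beyond all 3 of the other. The limma model called 1229 of 5054 genes, 598 higher and 631 lower with zinc, and 135 and 166 of these differed at least 2-fold. The balance depends on the processing, with 1200 higher and 282 lower in the authors' values and 428 and 692 after normexp correction. Genes whose arrays did not overlap between the groups made up 40.8%, against the 10% that chance gives.

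Both phosphate genes measured, pstA and pstC, which encode the membrane channel of the high-affinity phosphate transporter, rose. The log2 difference was 3.06 ± 0.15 (adjusted p = 1.55e-06) for pstA and 2.52 ± 0.31 (adjusted p = 0.000422) for pstC. The untreated pstA signal, at a mean log2 of -3.42, was near background, though at least 1 probe was called above it on all 3 arrays, and the size of the rise was 1.03 after normexp correction and 2.42 in the authors' values. For pstC these were 1.23 and 2.36. Of the 3 genes for iron-sulfur cluster assembly, hscB rose by 1.12 ± 0.14 and hscA by 0.82 ± 0.12, both encoding chaperones of that pathway, while cyaY differed by 0.36 and was not called. The list's median was 0.82 (adjusted p = 0.0256), but adjusted p = 0.359 with an estimated correlation and 0.117 with the slide as a block. Of the 6 chaperones and heat shock proteases, hslU, the ATPase of the HslUV protease, rose by 0.90 ± 0.10 and clpS also passed the test over all genes, and 2 passed adjusted over the list alone. The list was not called (adjusted p = 0.914) and its median of -0.21 and mean of 0.06 differed in sign. The clpS difference of 0.36 lost its call without untreated Δzur replicate 3 (0.26, adjusted p = 0.144) and without 6 of the other arrays in turn. The ferrochelatase gene hemH rose by 0.62 ± 0.09, and metX, for an enzyme of methionine synthesis, rose by 0.72 ± 0.15. With the slide as a block, hscA, hemH and metX rose by 0.66, 0.65 and 0.81 (adjusted p = 0.034, 0.016 and 0.040), and within slide 2, with 1 untreated array, the same differences had adjusted p = 0.072, 0.066 and 0.088.

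All 47 genes of ribosomal proteins fell with zinc, over all genes tested and adjusted over the list alone. Their median log2 difference was -0.99 (adjusted p = 1.34e-21), with adjusted p = 0.359 with an estimated correlation and 0.00550 with fry. The largest falls were rplV at -1.55 ± 0.21, rpsS at -1.52 ± 0.23, rpsC at -1.46 ± 0.21 and rplW at -1.40 ± 0.24. The 66 RNA locus tags had a median of -0.60 (adjusted p = 1.00e-08), and 17 of them fell over all genes and 22 adjusted over the list alone. Of 11 translation factors 6 fell, with a median of -0.42 (adjusted p = 0.00220), and of 16 aminoacyl-tRNA synthetases 6 fell, with a median of -0.27 (adjusted p = 0.00368), among them thrS at -0.75 ± 0.14. Of 7 genes of the transcription core 3 fell (median -0.40, adjusted p = 0.0256), and of 11 genes of DNA replication and recombination 2 fell (median -0.22, adjusted p = 0.0256). After quantile normalization these 2 lists had adjusted p = 0.0587 and 0.108. Adjusted over the list alone, 8 translation factors, 8 synthetases, 4 genes of the transcription core and 4 of DNA replication fell. In the authors' values, whose median over all genes was 0.22, the medians were -0.73 for the ribosomal proteins, -0.35 for the RNA locus tags, -0.11 for the translation factors, -0.0071 for the synthetases and -0.15 for the transcription core. Each of the lists of this paragraph had adjusted p = 0.359 with an estimated correlation.

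Further genes of growth and energy metabolism fell in smaller numbers. In the list of polyhydroxybutyrate and central carbon, gltD, for the small subunit of glutamate synthase, which serves nitrogen assimilation, fell by 1.43 ± 0.11 (adjusted p = 2.10e-05), and 1 of 5 members was called over all genes and 2 adjusted over the list alone. Of the 3 genes of the respiratory chain and ATP synthase, 2 fell over all genes and 3 adjusted over the list alone, among them atpC, for a subunit of ATP synthase, at -0.76 ± 0.13. Of 17 genes of nucleotide synthesis 5 fell and 1 rose. These 3 lists had medians of -0.26, -0.53 and -0.24 and adjusted p = 0.0399, 0.0256 and 0.0256, but adjusted p = 0.359 with an estimated correlation, and 0.0811, 0.0807 and 0.0807 with the slide as a block. The call of central carbon was also lost with the replicate number as a block (adjusted p = 0.0566) and after quantile normalization (adjusted p = 0.136). In the authors' values, whose median over all genes was 0.22, the medians of central carbon, nucleotide synthesis and DNA replication were 0.02, 0.02 and 0.03, and that of the respiratory chain -0.25. The zinc-dependent list, with 3 members, was not called (adjusted p = 0.30, but 0.0196 with fry). Its member rpmJ, a ribosomal protein gene, fell by 0.76 ± 0.12 over all genes and adjusted over the list alone. The members cysS and def differed by 0.10 and -0.17. In the list of protein export 5 of 15 genes fell and 1 rose, or 5 and 3 adjusted over the list alone (adjusted p = 0.168, but 0.0237 with fry). The gene secY, for the main channel of the export machinery, fell by 0.94 ± 0.15. With the slide as a block, thrS, rpmJ and secY fell by 0.79, 0.74 and 0.89 (adjusted p = 0.038, 0.035 and 0.036), and within slide 2, with 1 untreated array, the same differences had adjusted p = 0.067, 0.070 and 0.060.

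The other lists were not called for zinc with camera. With fry, amino acid, cell wall and cobalamin synthesis had adjusted p = 0.00562, 0.00860 and 0.0131. Flagella, DNA repair, hydrogenase and urease, cofactor synthesis and tRNA modification were not called with fry (adjusted p from 0.106 to 0.604). Flagella and motility had 1 of 19 members called, also adjusted over the list alone (median 0.07, adjusted p = 0.759), and that member, flgJ, was well above background in neither mutant group and had a log2 difference of 1.54 as reported but -0.047 after normexp correction. DNA repair had 1 of 9 higher over all genes and 0 adjusted over the list alone (adjusted p = 0.890), and hydrogenase, urease and nickel had 0 of 4 in either count (adjusted p = 0.509). Amino acid synthesis had 2 higher and 4 lower of 21 (adjusted p = 0.150), cell wall synthesis 3 lower of 14, or 2 higher and 4 lower adjusted over the list alone (adjusted p = 0.243), cofactor synthesis 1 higher and 1 lower of 26, or 1 and 0 adjusted over the list alone (adjusted p = 0.627), tRNA modification 2 lower of 13 (adjusted p = 0.243) and cobalamin synthesis 0 of 3 (adjusted p = 0.361). The list of sulfur assimilation held cysM and cysS, picked by the start of their symbols, which does not make cysS a gene of sulfur assimilation. Their log2 differences of 0.28 and 0.10 did not pass the test. With the slide as a block 651 genes were called for zinc, and 449 within slide 2. Leaving out an array gave 831 to 1180 calls.

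**Figure D1:**
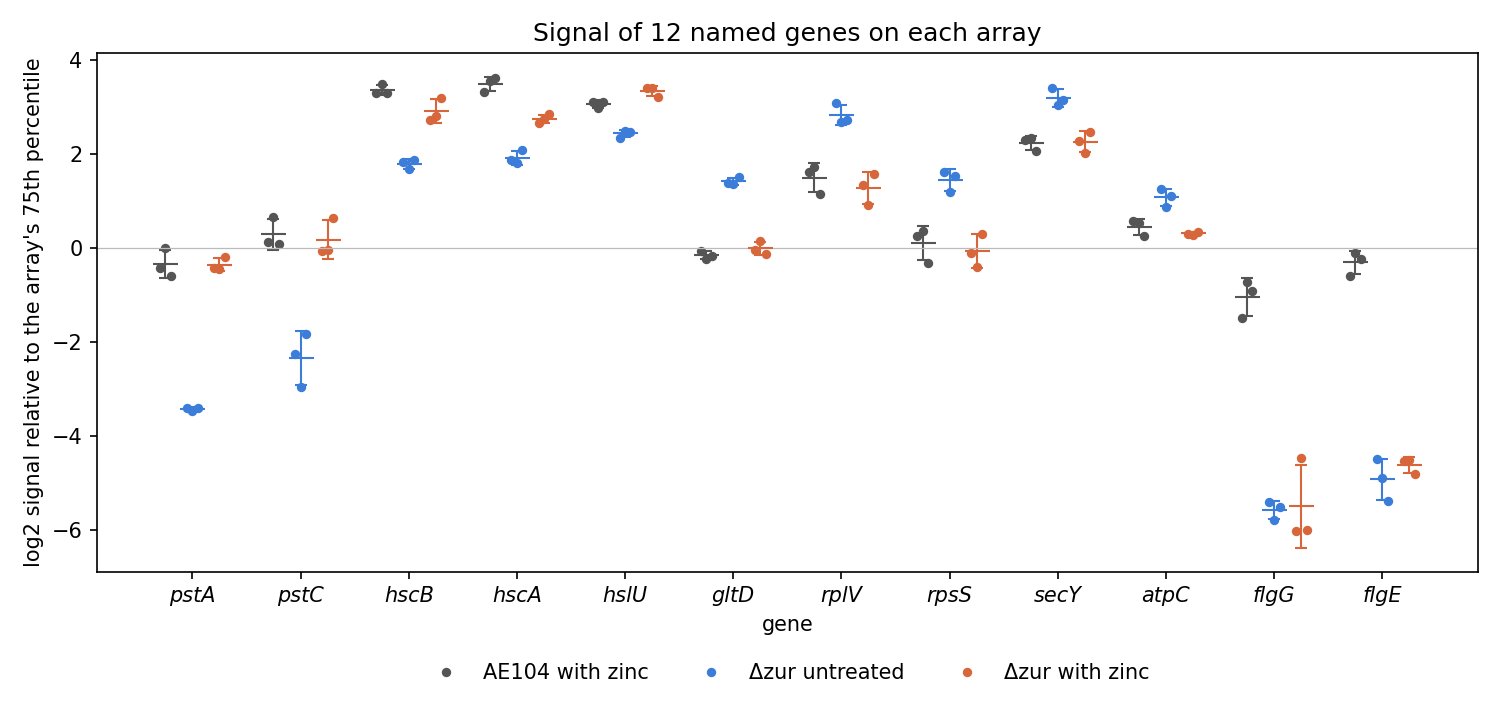
Log2 signal relative to the array's 75th percentile (y axis) of 12 named genes (x axis) on each of the 9 arrays. Points are arrays, bars are the group mean and SD (n = 3), and the pstA points of untreated Δzur lie near -3.42 while those of both zinc-treated groups lie near -0.34 and -0.35.

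The second comparison set Δzur against AE104, both with zinc, and asked how the mutant differed when zinc was present. The mutant had lower transcripts of the flagellar genes, from hook and rod to motor and export apparatus, and higher transcripts of blocks of neighbouring locus tags that were near background in AE104. Rmet_1098 was at least 486-fold and Rmet_1103 at least 379-fold higher in the mutant, with no AE104 array above background for either gene. Rmet_5252 was lower by a log2 difference of -6.10 ± 0.22 (adjusted p = 3.82e-08) and Rmet_3683 by -4.41 ± 0.24 (adjusted p = 9.23e-07). The model called 359 of 5054 genes, 211 higher and 148 lower in the mutant, and 159 and 75 of these differed at least 2-fold. Non-overlapping genes made up 25.3%, against the 10% of chance. No slide held both groups, so the difference has no value within a slide, and with the slide as a block, estimated through the untreated mutant, 208 genes were called.

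Of the 19 flagellar and motility genes tested, 17 were lower in the mutant, and 18 adjusted over the list alone. The median log2 difference was -3.12 (adjusted p = 4.72e-25), and the call held with an estimated correlation (adjusted p = 0.0482). Because 14 members were above background on no array of the mutant, the median with these at their bound was -2.22. The hook gene flgE was at least 12-fold lower, and the rod genes flgF and flgG at least 12.7-fold and 7.23-fold lower. The hook-filament junction gene flgL, detected on all arrays of Δzur with zinc, was lower by a log2 difference of -3.88 ± 0.25 (adjusted p = 3.58e-06). Set at their bounds, the stator gene motB and the motor switch gene fliG had log2 differences of -2.80 and -1.40. The smallest differences were -0.52 for fliF and -0.23 for fliQ, which did not pass the test over all genes. After normexp correction, which adds an offset to dim signals, the median was -0.55 with 16 members called lower, and in the authors' values it was -1.65.

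Among the other named genes, hscA was lower in the mutant by a log2 difference of -0.75 ± 0.12 (adjusted p = 0.00327), with a mean log2 signal of 2.74 against 3.49 in AE104, and hscB differed by -0.45 without a call, while adjusted over the list alone 1 of the 3 genes for iron-sulfur cluster assembly was higher and 2 were lower. The arginine synthesis gene argD was higher by 0.74 ± 0.11, and by the same 0.74 but without a call with the slide as a block (adjusted p = 0.160). The phosphate genes pstA and pstC differed by -0.01 and -0.11 and the ribosomal proteins had a median of -0.08, with 0 of 47 called over all genes or adjusted over the list alone. No list other than flagella was called, with adjusted p from 0.112 for the RNA locus tags, which had adjusted p = 0.0361 with the slide as a block, to 0.891 for cobalamin synthesis. The counts over all genes and adjusted over the list alone were 0 for chaperones, the respiratory chain, zinc-dependent enzymes, hydrogenase and urease, DNA repair and central carbon. The median of 0.05 and the mean of -0.01 of DNA repair differed in sign.

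Most genes higher in the mutant lay in runs of locus tags, a pattern searched for after the values were seen. The search found 4 segments of higher tags, numbered 1098 to 1104, 1239 to 1338, 3012 to 3046 and 5689 to 5753, whose tested tags had median log2 differences of 9.49, 3.40, 3.18 and 3.16, or 8.83, 2.13, 1.81 and 1.41 with tags undetected in AE104 at their bound. They held 137 of the 211 higher genes and 134 of the 159 that were at least 2-fold higher. A further 2 segments were lower in the mutant, 3678 to 3703 with a median of -3.28 and 5252 to 5265 with a median of -2.41, or -3.13 and -2.15 with bounds. None of 1000 permutations of the tag order gave any segment in either direction (permutation p = 0.001, the smallest they can give). The permutations treat neighbouring tags as independent, so they cannot tell the segments from ordinary co-expression of neighbouring genes. Without the tags of the 4 higher segments 191 genes were called, 58 higher and 133 lower, and with a probe well above background on all 9 arrays 139 were called, 60 higher and 79 lower.

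**Figure D2:**
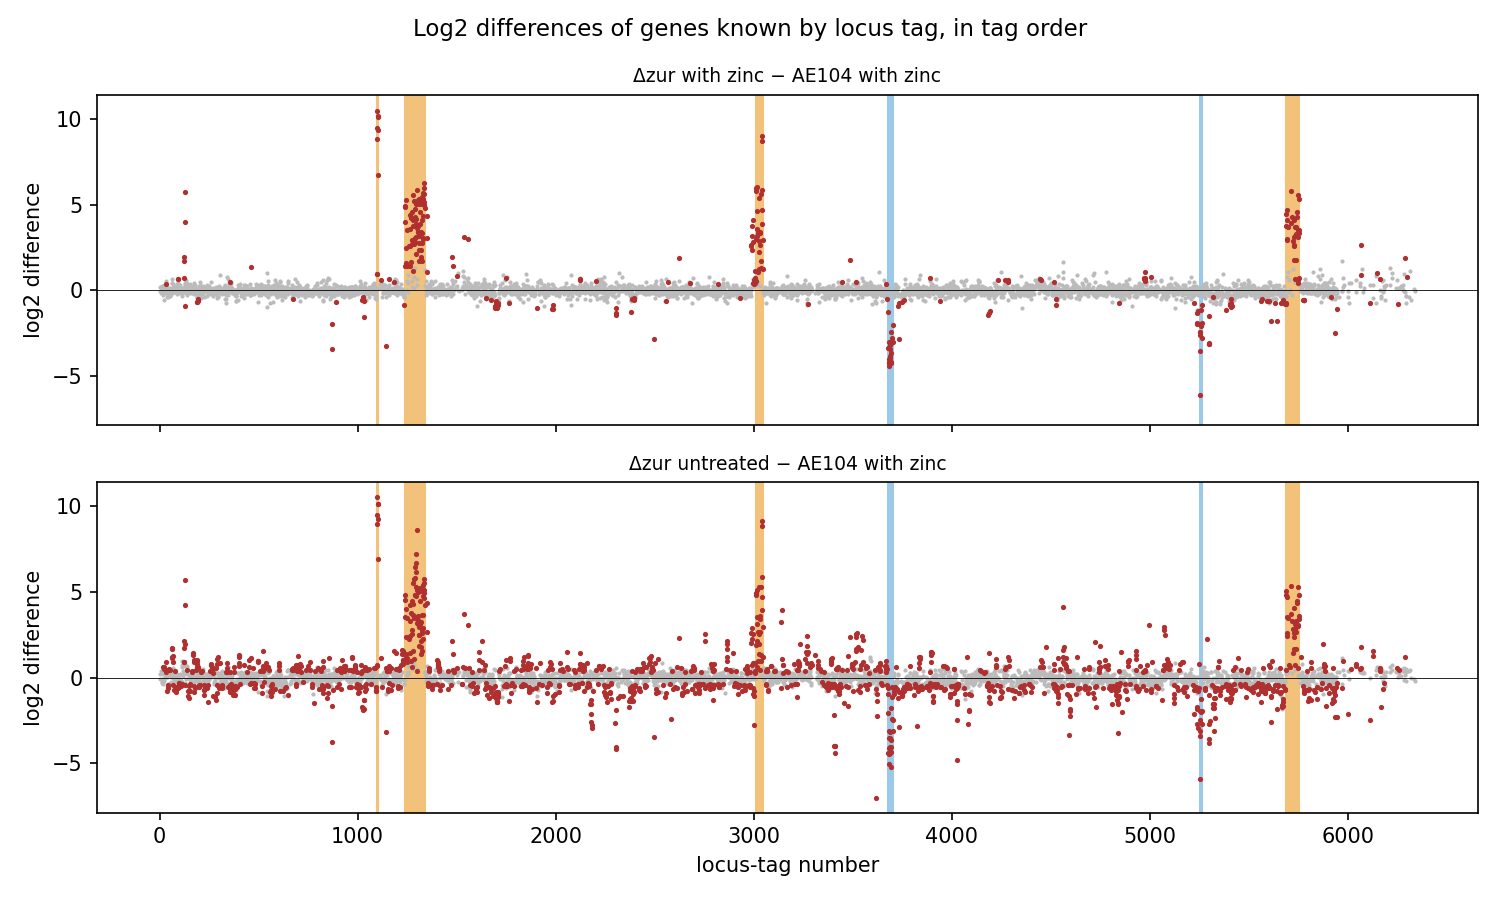
Log2 difference (y axis) of each tested gene known by locus tag against its tag number (x axis), for Δzur with zinc minus AE104 with zinc and for untreated Δzur minus AE104 with zinc. Red points were called (adjusted p below 0.05), orange bands are the 4 segments higher and blue bands the 2 segments lower in the mutant, and the first orange band has a median log2 difference of 9.49 in the upper panel.

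The third comparison, untreated Δzur against AE104 with zinc, changed both genotype and zinc, so it cannot separate the 2 factors. Flagellar genes were lower and ribosomal protein genes higher in the untreated mutant, and the phosphate transporter and iron-sulfur chaperone genes were lower. All 47 ribosomal protein genes rose, over all genes and adjusted over the list alone, with a median of 0.90 (adjusted p = 1.90e-14, but adjusted p = 0.595 with an estimated correlation), for example rpsS by 1.35 ± 0.23 and rplV by 1.33 ± 0.21. Of the 19 flagellar genes 18 were lower in both counts, with a median of -3.02, or -1.80 with undetected members at their bound (adjusted p = 0.264 with an estimated correlation). After normexp correction this median was -0.45, and in the authors' values -1.75. Rmet_1098 was at least 503-fold and Rmet_1103 at least 370-fold higher, and Rmet_3620 fell by 6.99 ± 0.15 and Rmet_5252 by 5.92 ± 0.22. The differences were -3.07 ± 0.15 for pstA, -2.63 ± 0.31 for pstC, -1.57 ± 0.12 for hscA and -1.57 ± 0.14 for hscB, and 1.57 ± 0.11 for gltD, 1.35 ± 0.11 for argD, 0.96 ± 0.15 for secY and 0.84 ± 0.12 for rpmJ. The model called 1692 genes, 833 higher and 859 lower, of which 290 and 237 differed at least 2-fold, and 1104 were called within slide 1. In the authors' values 428 were higher and 1343 lower, and after normexp correction 771 and 549. Non-overlapping genes made up 48.0%, against the 10% of chance.

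Translation factors, with 6 of 11 higher over all genes and 8 adjusted over the list alone (median 0.39, adjusted p = 0.0106), and the RNA locus tags, with 12 of 66 higher over all genes but 0 adjusted over the list alone (median 0.39, adjusted p = 0.00164), were also called in the third comparison, with adjusted p = 0.595 and 0.608 with an estimated correlation, and the RNA locus tags had adjusted p = 0.149 after quantile normalization and 0.123 with fry. In the authors' values the medians were 0.12 and 0.14, and that of the ribosomal proteins 0.66, against a median of -0.19 over all genes. The remaining lists were not called with camera, with adjusted p from 0.0952 for the aminoacyl-tRNA synthetases, of which 4 were higher over all genes and 7 adjusted over the list alone, to 0.940 for the chaperones, of which 1 was lower in both counts. With fry, chaperones, DNA repair, DNA replication, cofactor synthesis, protein export and tRNA modification were not called either (adjusted p from 0.0817 to 0.952). The others of these lists were called with fry, with adjusted p from 0.000274 for central carbon to 0.0286 for cell wall synthesis. Of the respiratory chain 2 were higher over all genes and 3 adjusted over the list alone, of central carbon 1 and 4, and of the zinc-dependent list 1 and 1. DNA repair and hydrogenase and urease had 0 called in either count. The chaperones' median of 0.07 and mean of -0.01 differed in sign.

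**Figure D3:**
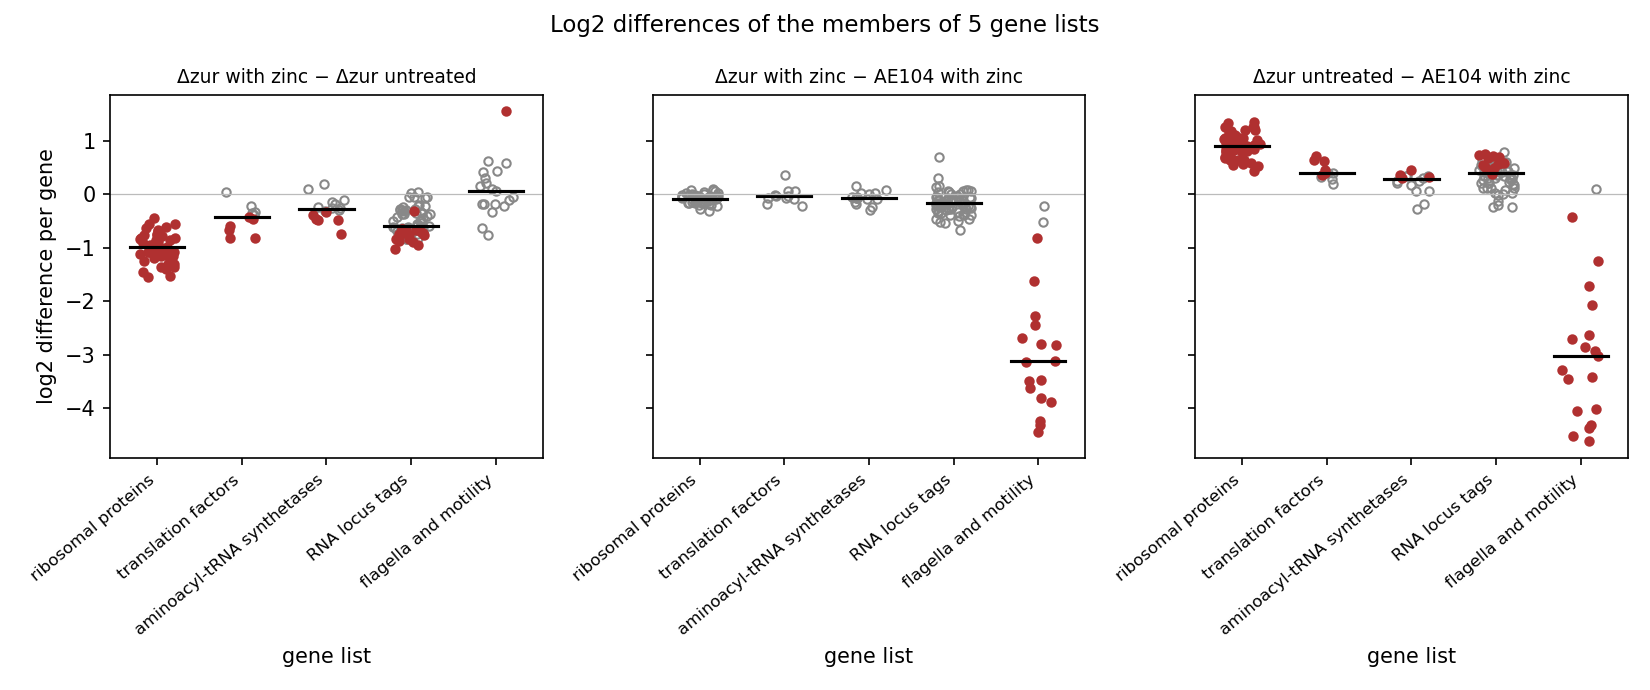
Log2 difference (y axis) of each tested member of 5 gene lists (x axis) in the 3 comparisons. Filled red points were called (adjusted p below 0.05), open points were not, black lines are medians, and the ribosomal protein medians are -0.99, -0.08 and 0.90 from left to right.

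Genes that differed from AE104 in the same direction in both mutant groups numbered 312, of which 187 were higher and 125 lower, and these are differences from AE104 found with and without zinc in the mutant. Independent calls would share 34.8 and 25.2 genes, a level that leaves out the noise of the AE104 arrays used in both comparisons. A further 12 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 differences of the 2 comparisons correlated at 0.832, with 0.498 in the simulations from the shared arrays alone. The shared genes included 135 higher tags of the segments, and without the segment tags 158 genes were shared.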

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

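The tests of the slides, of wrong labels, of missing DNA, of the scaling and of the dimmest array, and the search for segments, were chosen after the results were seen, whereas the counts over other splits of the arrays and the test on bright probes were fixed beforehand.

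Probes between genes gave signals that the comparisons of genes do not use. Of 3417 intergenic features 2431 were tested, and 472 were called for zinc in Δzur (227 higher, 245 lower), 121 for Δzur against AE104 with zinc (79 higher, 42 lower) and 706 for untreated Δzur against AE104 with zinc (383 higher, 323 lower). Of 226 intergenic features named for the 2 plasmids that AE104 lacks, 32 were well above background on all 9 arrays, 14.2% (95% exact interval 9.89% to 19.4%), against 62.5% of those named for the chromosomes.

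The 3 long segments of locus tags, 1239 to 1338, 3012 to 3046 and 5689 to 5753, held 123 genes at least 2-fold higher in both mutant groups than in AE104. For untreated Δzur, the median log2 difference within slide 1 argues against a difference between the slides. It was 1.69 over the 160 tested tags of the matching segments found without the untreated arrays, with undetected values at the floor (95% interval over arrays 1.43 to 1.96). That search also found tags 2987 to 2996, with 8 tested tags, which matched no long segment and were left out. The long segments were found with all arrays, so this match let the untreated arrays bear on the choice of tags. Δzur with zinc shares no slide with AE104 and has no such value. A wrong label on 1 or 2 AE104 arrays is contradicted by median deficits of 1.78, 1.69 and 1.92 on replicates 1, 2 and 3, each in the segments found without that array and with the same floor (95% interval over genes for the smallest 1.49 to 2.03). Whether the segments were absent from the DNA of the AE104 cultures cannot be told apart from low expression. Of the 129 segment tags detected on all 6 mutant arrays, 32 were detected on all 3 AE104 arrays and 83 on no AE104 array. The share of 24.8% (95% exact interval 17.6% to 33.2%) has an interval that overlaps that of the plasmid features. These shares are unlike, since the plasmid features were intergenic, were not chosen by detection in the mutant and had to be detected on all 9 arrays. An effect of the zur deletion, and another difference between the AE104 and mutant cultures, were not tested and stay open.

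The flagellar genes were lower in each mutant group than in AE104 with zinc, with 17 of 19 called in Δzur with zinc and 18 in untreated Δzur, where the list's call was lost with an estimated correlation (adjusted p = 0.264). AE104 without zinc was not measured. For untreated Δzur, the slides as the whole cause are contradicted by a median log2 difference of -1.82 within slide 1 with undetected values at the floor (95% interval over arrays -2.58 to -1.08). That comparison also changed zinc, and Δzur with zinc has no value within a slide. The scaling between arrays is contradicted by a median of -2.35 after quantile normalization, with the same floor (95% interval over arrays -2.96 to -1.82). That value, for Δzur with zinc, does not cover the handling of background. After normexp correction the median was -0.55 in Δzur with zinc and -0.45 in untreated Δzur. The deletion itself and other differences between the strains' cultures, such as an altered background of one of them, stay open and untested.

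The ribosomal protein genes were lower with zinc in the mutant. Within slide 2, where the slide is constant, the median was also negative at -0.91, but it rests on 1 untreated array, too few to exclude a difference between the slides. Without the dimmest array, untreated Δzur replicate 1, the median was -0.90 (95% interval over arrays -1.49 to -0.28), which goes against that array as the whole cause. Relative to the 20 genes nearest in signal it was -0.84 (95% interval over genes -0.97 to -0.77), which goes against an effect on bright probes alike. The treatment with zinc stays open as a biological explanation, and a difference in growth between the untreated and treated cultures was not tested.

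For each of the 3 comparisons, 6 arrays can be split in 10 ways, too few for a share below 0.05. In each, 1 of the 10 splits, the real one, gave as many genes: 1229, 359 and 1692, with 0 genes as the highest count of the other splits. For the genes shared by both mutant groups, 2 of 100 regroupings of the 9 arrays gave at least the real 312, and 1 of these was the real grouping. The other was the highest, with 794 genes. It took the 3 untreated Δzur arrays as the shared group and mixed the 6 zinc-treated arrays, which points to a structure of the samples in which the untreated arrays stand apart from both zinc-treated groups, and the next highest gave 242. Most other regroupings mix groups that differ, which widens the spread within a group and can lower the counts. The share of regroupings therefore does not decide on chance.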

How the results depend on the processing

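Comparisons within a slide, numbered gene parts kept apart, intergenic features tested with the genes and the exclusion of segment tags were chosen after the data were seen. The slide as a block was not planned for the gene lists. With the slide as a block, 651 genes were called for zinc, 208 for Δzur against AE104 with zinc and 196 shared by both mutant groups. Within slide 2 the zinc count was 449, and within slide 1 that of untreated Δzur against AE104 was 1104, with fewer arrays in each. With a probe well above background on all arrays, 139 genes differed between Δzur and AE104 with zinc and 109 were shared. Of the 359 genes called as reported between Δzur and AE104, 161 passed this filter. The zinc count was 1237 with the filter, against 1229 as reported. Without the segment tags these counts were 191 and 158. A minimum of 2-fold left 301 genes for zinc, 234 for Δzur against AE104 and 527 for untreated Δzur against AE104. Leaving out each array gave 831 to 1180 genes for zinc, 291 to 380 for Δzur against AE104, 1198 to 1674 for untreated Δzur against AE104 and 265 to 306 shared. Every other setting run kept these 4 counts within 1.5 times. With the replicate number as a block they were 1231, 384, 1702 and 318. In 5 of 9 pairs, arrays with the same number in different groups correlated above 0.1 after their group means were removed (range -0.09 to 0.27), and 4 of 9 arrays correlated best with their own number in both other groups, so the numbers were not read as pairs.

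The share of higher genes moved by over 10 points in 6 cases. For zinc it was 48.7% as reported, 38.2% after normexp correction and 81.0% in the authors' values. It was 24.2% against 49.2% in the authors' values for untreated Δzur against AE104, and 70.2% against 58.8% for Δzur against AE104 with the slide as a block, and the causes of these 4 shifts were not tested. For Δzur against AE104 the majority turned to lower genes, with 43.2% higher with a probe well above background on all arrays, where fewer genes were tested, and 30.4% without the tags of the higher segments, which that setting removes. The authors' values shifted the median of all genes by 0.17 for zinc and by -0.18 for untreated Δzur against AE104, and normexp shifted it by -0.13 for zinc.

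Of 160 results for 110 named genes 79 kept their call in every setting run, and of 63 results for 21 gene lists 32 kept their side of the threshold. The slide as a block ended 58 of the gene calls and the authors' values 50, besides the reversed ispH__2. The difference of flgJ for zinc reversed to -0.047 after normexp correction (adjusted p = 0.765), and that of ispH__2 in untreated Δzur against AE104 to -0.13 in the authors' values (adjusted p = 0.532), for causes that were not tested. With fry in place of camera, 16 list results that were not called as reported were called, and 1 list call was lost. An estimated correlation ended 14 list calls. The only call it left was that of flagella and motility in Δzur with zinc against AE104 with zinc (adjusted p = 0.0482). The planned result for the zur signal was not run, because the files do not tie zur to a probe. Signal over background limits both falls and rises. Among the falls, 14 of 19 flagellar genes were at background in Δzur with zinc. In the same comparison with AE104, many tags of the higher segments were detected on no AE104 array. In tag order, those that were also detected in Δzur with zinc and had a bound were 4 of 7, 56 of 83, 19 of 31 and 27 of 41 tested tags. Tags undetected in both groups are not in these counts. In the lower segments, 5 of 22 and 3 of 10 tested tags had a bound, with detection on no array of Δzur with zinc.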

Other observations

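The overlap between the comparisons described here was examined after the results were seen. Of the 598 genes higher with zinc, 466 were lower in untreated Δzur than in AE104 with zinc, and of the 631 lower with zinc, 485 were higher. The untreated arrays enter both comparisons with opposite sign, so such an overlap is expected from their shared noise, and agreement beyond that was not tested. Of the same genes, 537 and 592 were not called between Δzur and AE104 when both had zinc, which does not show that their levels were equal. The phosphate transporter gene pstA had mean log2 signals of -0.34 ± 0.30 in AE104 with zinc, -3.42 ± 0.03 in untreated Δzur and -0.35 ± 0.14 in Δzur with zinc (SD, n = 3). For gltD, of glutamate synthase, the means were -0.15 ± 0.08, 1.42 ± 0.07 and -0.01 ± 0.14.

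Of genes picked after their values were seen, the export gene secY had mean log2 signals of 2.24, 3.20 and 2.25 in AE104 with zinc, untreated Δzur and Δzur with zinc, and atpC of ATP synthase 0.45, 1.08 and 0.31. The iron-sulfur chaperone gene hscA took a middle level in Δzur with zinc, at 3.49, 1.92 and 2.74 in the same order. Of the plasmid intergenic features 41 were tested, and 1, 0 and 5 were called for zinc, for Δzur against AE104 with zinc and for untreated Δzur against AE104 with zinc.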
